A study of Mus musculus with 19 samples.

How the data were processed

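The data came from neural progenitor cells (NPCs) of the mouse cortex at embryonic day 17.5, cultured on Matrigel with bFGF and EGF. Cells were wild type (WT) or carried a conditional knockout (cKO) of Mettl8, which encodes a mitochondrial RNA methyltransferase that makes 3-methylcytidine (m3C) in tRNA. RNA-seq libraries (SMART-seq2, 300 ng of total RNA) came from 6 cKO and 6 WT samples. Libraries for hydrazine-aniline cleavage sequencing (HAC-seq, 8000 ng of total RNA) came from 3 cKO and 4 WT samples. In HAC-seq, hydrazine attacks m3C and aniline cleaves the chain there, so reads from a modified molecule start 1 nucleotide downstream of the cytidine. Groups and replicate numbers are those of the labels. The labels do not say that replicates are separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

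Per the submitters' processing notes, the authors used bcl2fastq 2.17.1.14, Trimmomatic 0.32 and STAR 2.5.2a, with mouse build GRCm38 for RNA-seq and GRCm38.p6 for HAC-seq. The counting program, its annotation and the trimming settings are not given in the sources used here. The deposited RNA-seq table holds raw read counts per gene without normalization. The deposited HAC-seq table lists C sites and, per the file headers, keeps a site only if more than 1 read in each WT library starts 1 bp downstream. The filter was checked on the table, where the smallest WT number was 2. For each library the authors give the number of such read starts (a coverage signal), the count of all reads at the site, called coverage here, and their quotient, the cleavage ratio, as a fraction. Recomputed quotients differed from the deposited fraction by at most 5.55e-16. The authors also give a p-value per site, whose test is not named in the sources used here. Ratios are given as percentages below. All sample columns were used and the number left out was 0.

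The RNA-seq table held 26621 genes, of which 6309 had no read in any library. Counts from 1 to 10 were odd in 17.4% of cases, against 50.1% of counts from 101 to 1000, a pattern that counting both mates of a read pair would give. An alternative therefore divided all counts by 2. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by genotype kept 13105 genes, libraries were scaled by TMM, and genotype was tested by the two-sided quasi-likelihood F test with library set as a covariate. The library names give 2 sets, each with both genotypes: set 1 holds cKO replicates 1 and 2 with WT replicates 1 to 3, and set 2 holds cKO replicates 3 to 6 with WT replicates 4 to 6. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels are TMM-scaled read counts relative to library size (CPM), fold changes are cKO over WT on the log2 scale with the standard error (SE) from the F statistic, and log2 CPM for lists used a prior count of 2. The same test was applied to the interaction of genotype and library set. DESeq2 1.42.0 and limma 3.58.1 (voom) served as alternatives. The median log2 fold change of all genes was -0.000996.

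Genes were grouped in 29 lists. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 23 lists tested. The correlation estimated from the libraries, and limma's fry, which asks whether a list's genes move together without comparing them with other genes, were run beside it. The lists were m3C methyltransferases and partners, mitochondrially encoded mRNAs, nuclear genes of complex I and of complexes II to V, the mitochondrial translation machinery, ATF4 targets of the integrated stress response, mitochondrial chaperones and proteases, glycolysis, antioxidant response and cholesterol synthesis. Further lists covered G1/S and G2/M genes of the cell cycle, p53 targets, Notch, Wnt and interferon genes and extracellular matrix genes. Cell type lists covered neural stem cells and radial glia, intermediate progenitors, neurons, the ventral and interneuron lineage, astrocytes, oligodendrocytes, microglia, endothelium and mural cells, meningeal fibroblasts and ependyma. X inactivation and Y-linked genes served as a check of embryo sex.

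Of 135582 entries in the HAC-seq table, 16692 repeated a site, which left 118890 sites. Sites with coverage of at least 50 in each of the 7 libraries and a mean ratio of at least 0.05 were tested, 13240 in all. Of these, 838 had the same read starts and coverages as another tested site, as reads shared between repeated genes would give. Read starts out of coverage were fitted by a quasi-binomial model with genotype as the term. Dispersions were squeezed across sites by limma's squeezeVar and not allowed below 1, and the F test was two-sided with Benjamini-Hochberg adjustment. Single sites and means over sites were compared by exact permutation of the 35 splits of 7 libraries into 3 and 4. The smallest p this design allows is 0.0286. Intervals are exact Clopper-Pearson intervals at 95%, and a count of 0 is given with the share that 3 counts would make. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Positions within tRNA genes came from the RefSeq annotation of GRCm38.p6. The reference genome sequence was not used here.

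Both tests were tried on simulated data with the design of the real libraries. For RNA-seq, 50 genes each were changed at 4 sizes among 12928 tested. The test called 44% of genes changed 1.25-fold, 86% at 1.5-fold, 100% at 2-fold and 100% at 4-fold, with 13 unchanged genes called. These rates cover the simulated genes only and were not split by expression, so they are not known for genes of low expression. In the real libraries Mettl8 was 1.59 times higher in cKO and was not called (edgeR adjusted p = 0.265). The rates may therefore be too high for real genes. A lack of called genes does not exclude changes of these sizes. For HAC-seq, 50 sites each were given lower odds of cleavage in cKO. With sites drawn from any tested site, 0% were called at 1.5-fold lower odds, 8% at 2-fold, 12% at 4-fold and 48% at 20-fold. A second simulation, added after this result was seen, drew sites with coverage of at least 200 and a ratio of at least 0.10 and gave 28%, 72%, 100% and 100%. At most 4 unchanged sites were called in either. The simulations did not separate coverage from the ratio.

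Tests, lists, most alternatives and the rule for named genes and sites were chosen before the data were examined. The rule named Mettl8 and the m3C methyltransferases, the 10 genes of largest rise and the 10 of largest fall past the threshold with log2 CPM of at least 3 and the same sign in both library sets, and from each list up to 3 members past the threshold or, where none passed, the 2 of highest expression. It named position 32 of mt-tRNA-Thr and mt-tRNA-Ser(UCN), every site past the threshold if there were 10 or fewer, and the 6 other sites of highest ratio. Other genes are marked as chosen after their values were seen. Some genes that the rule named are not reported here. Alternatives changed the test, scaling, filters, covariates, libraries and thresholds, and left out each library in turn. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.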

Results

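Neural progenitor cells (NPCs) are the dividing cells of the embryonic brain that give rise to neurons and glia. Here they came from the mouse cortex at embryonic day 17.5 and were grown as cultures, either wild type (WT) or with a conditional knockout (cKO) of Mettl8. The study asked which 3-methylcytidine (m3C) sites depend on Mettl8 and how gene expression differs without it. HAC-seq was done on 4 WT and 3 cKO libraries. Median coverage at the 13240 tested C sites ran from 140 to 196 reads in the WT libraries and from 113 to 148 in the cKO libraries. RNA-seq was done on 6 WT libraries with a total of 17.0 ± 1.62 M counts (SD, n = 6) and 6 cKO libraries with 14.5 ± 1.46 M (SD, n = 6), with a range of 11830839 to 18863781. Libraries fell into 2 sets by name, and the first principal component, with 48.5% of the variance, separated the sets.

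The cytidine at position 32 of mitochondrial tRNA-Thr was almost fully cleaved in WT NPCs and almost uncleaved in cKO NPCs. This site lies in the anticodon loop, at nucleotide 29 of mt-Tt (chromosome MT, plus strand, position 15317 in GRCm38.p6; RefSeq gene TrnT, 15289 to 15355). Cleavage was 94.4% ± 0.483 (SD, n = 4) in WT and 2.10% ± 0.405 (SD, n = 3) in cKO, a difference of -92.3 percentage points or a 44.9 times lower level. The 4 WT libraries gave 93.7%, 94.6%, 94.7% and 94.7%, and the 3 cKO libraries gave 2.11%, 1.70% and 2.51%. Coverage was 1767 to 4224 reads, so that each library's Clopper-Pearson interval was narrow, from 92.7% to 94.6% in WT replicate 1 and from 1.15% to 2.41% in cKO replicate 2. The exact permutation p was 0.0286, one-sided and two-sided, the smallest that 3 against 4 libraries allow. The quasi-binomial fit over all tested sites gave an adjusted p of 5.8e-12 (limma's squeezed dispersions). The p-value in the authors' deposited table was 2.26e-11.

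**Figure D1:**
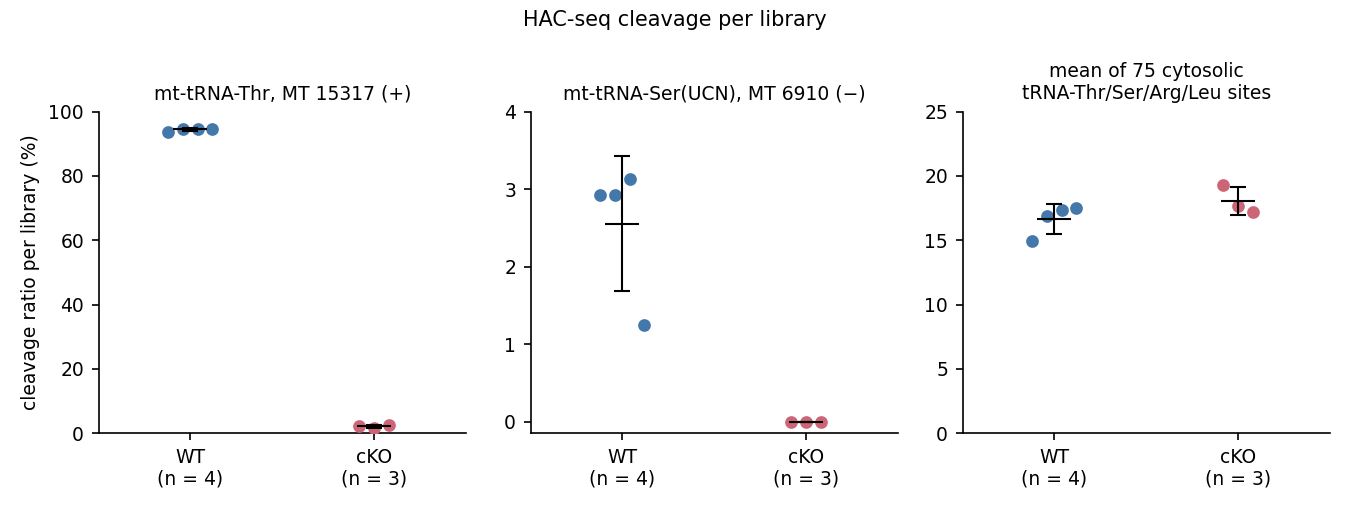
Cleavage ratio in percent for each HAC-seq library at mt-tRNA-Thr and mt-tRNA-Ser(UCN) position 32 and as the mean of 75 cytosolic tRNA sites; each point is a library, and lines show the mean ± SD for WT (n = 4) and cKO (n = 3). At mt-tRNA-Thr the WT libraries lie between 93.7% and 94.7% and the cKO libraries between 1.70% and 2.51%.

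Mitochondrial tRNA-Ser(UCN), another known METTL8 substrate, had a low cleavage ratio at position 32 in WT NPCs, and no cleaved read was seen in cKO NPCs. The site is nucleotide 29 of mt-Ts1 (chromosome MT, minus strand, position 6910; RefSeq gene TrnS1, 6870 to 6938). Cleavage was 2.55% ± 0.877 (SD, n = 4) in WT, with 2.92%, 2.92%, 3.13% and 1.25% in replicates 1 to 4. The cKO libraries had 0 of 1737, 0 of 1623 and 0 of 2050 reads, which allows a share of up to 0.173%, 0.185% and 0.146%. The exact permutation p was 0.0286 one-sided, lower in cKO as fixed in advance, and 0.0571 two-sided, so by permutation the fall passed only the one-sided test. With a mean ratio of at least 0.01, a filter chosen after seeing the data, the two-sided quasi-binomial test gave an adjusted p of 8.67e-04. Mean cleavage lay below the main site filter, so this site was not among the 13240 tested, and the p-value in the authors' deposited table was 0.0101. A position in Myo3a on chromosome 2 (22588065, plus strand) carried identical numbers, so the reads of mt-Ts1 are not told apart from those of this nuclear copy. Coverage itself, scaled between libraries, was 354 ± 36.4 (SD, n = 4) in WT and 2050 ± 78.9 (SD, n = 3) in cKO, 5.78 times higher (exact permutation p = 0.0286, two-sided). The WT ratio of 2.55% may therefore not give the share of modified molecules. If cleaved fragments were lost before counting, which was not tested, it would be too low.

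mt-tRNA-Thr was the only site past the threshold among the 13240 tested, with 1 site lower and 0 sites higher in cKO. At an unadjusted p under 0.05 the same quasi-binomial model gave 275 sites lower and 872 higher. Of these, 53 lower and 7 higher were among the 81 tested sites of the mitochondrial ribosomal RNAs, where mean cleavage was 7.67% in cKO replicate 3 and 13.4% to 16.1% in the other 6 libraries. Over all tested sites limma on the arcsine square root of the ratio gave 1042 sites at an unadjusted p under 0.05 and 1 after adjustment. By the authors' deposited table, a p under 0.05 was given to 535 of these sites and 1 passed after Benjamini-Hochberg adjustment. The 6 other sites of highest ratio, in Cfap61, Rbl1, Atp5o/Itsn1, Klf8, Atp5b/Snord59a and tRX-Lys-NNN-22-1, had ratios of 99.3% to 100% in both genotypes and differed by -0.347 to 0.386 points. Without an untreated library among the samples, reads that start at an RNA end are not told apart from cleavage at m3C. A ratio above 50% in WT was seen at 204 sites, and among all tested sites mt-tRNA-Thr alone fell by more than 20 points. These counts rest on cKO replicate 2: without it 13 sites were lower and 17 higher, and without cKO replicate 1 a site in the ribosomal RNA gene CT010467.1 was called lower besides mt-tRNA-Thr (2 lower). Not all sites called without cKO replicate 2 are independent. Several higher ones had equal means (12% in WT and 15.9% in cKO over all libraries), such as Gm25679, Gm26444 and Gm22317. Most of the lower ones were in the mitochondrial ribosomal RNAs. Across the 13240 sites 8124 were higher in cKO, with a median difference of 0.57 points.

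**Figure D2:**
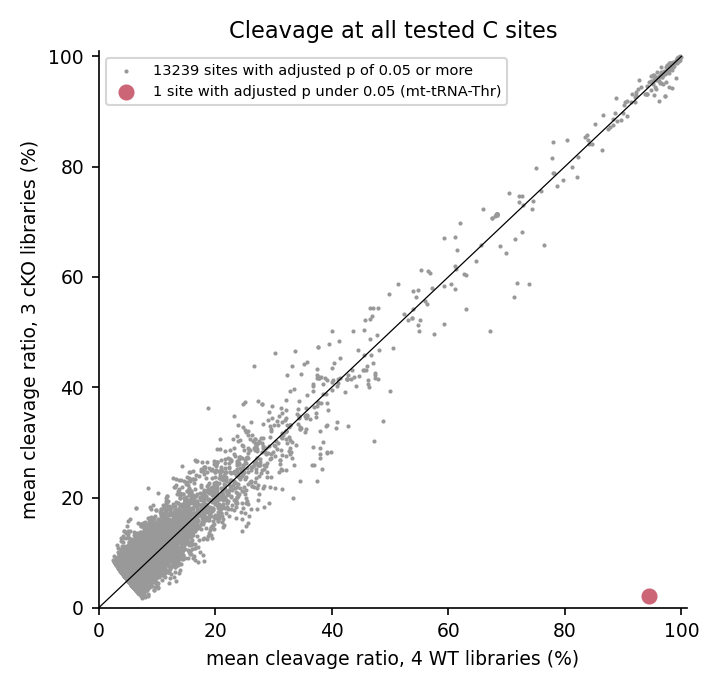
Mean cleavage ratio in percent of each of the 13240 tested C sites in 4 WT libraries (horizontal axis) and 3 cKO libraries (vertical axis), with the line of equal values. The red point is mt-tRNA-Thr position 32, at 94.4% in WT and 2.10% in cKO.

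Cytosolic tRNA-Ser and tRNA-Arg, whose m3C is made by other methyltransferases, were cleaved in both genotypes and served as the background measured in the same way. Over 75 C sites in cytosolic tRNA-Ser, tRNA-Arg, tRNA-Thr and tRNA-Leu genes cleavage was 16.7% ± 1.18 (SD, n = 4) in WT and 18.0% ± 1.09 (SD, n = 3) in cKO, a difference of 1.37 points that was not past the threshold (exact permutation p = 0.171, two-sided). It was 0.759 points without WT replicate 1, 0.815 without cKO replicate 1 and 0.0768 for the median over sites. Only 7 of these sites were at nucleotide 32, and they averaged 37% in WT and 40% in cKO (3.04 points, exact permutation p = 0.343, two-sided), an average chosen after the data were seen. The 8 tRNA-Ser sites averaged 51.7% in WT and 56.4% in cKO, and the 26 tRNA-Arg sites 19.4% and 21.6%. The 38 tRNA-Leu sites averaged 8.20% and 8.40%, and the 3 tRNA-Thr sites 6.46% and 6.09%. Of the sites at nucleotide 32, 6 were in tRNA-Arg, 1 in tRNA-Ser, 0 in tRNA-Leu and 0 in tRNA-Thr. The mean over 75 sites is therefore mostly over other nucleotides, and these data do not show which of them carry m3C. At nucleotide 32 of tRNA-Arg-CCT-2-1 (chromosome 11, position 115413345, minus strand) cleavage was 56.8% ± 7.02 (SD, n = 4) in WT and 60.8% ± 2.54 (SD, n = 3) in cKO at a coverage of 55 to 102. Of the 75 sites in these 4 tRNA families 49 were higher in cKO (8 of 8 in tRNA-Ser and 20 of 26 in tRNA-Arg), and 0 were called by the quasi-binomial model. Among all 296 tested cytosolic tRNA sites 217 were higher in cKO, with 75 higher and 5 lower at an unadjusted p under 0.05 and 0 called by the same model. These sites are not all independent, since some are the same nucleotide in copies of a gene. Most of the 8 tRNA-Ser sites were nucleotide 50 in copies of tRNA-Ser-AGA-2, at 46.6% to 75% in WT. The tRNA-Ser site at nucleotide 32 was at 24.8% in WT and 25.8% in cKO.

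In the RNA-seq libraries, Mettl8 transcripts were more abundant in the libraries labelled cKO than in WT. Mettl8 (chromosome 2, 70964561 to 71056388 in GRCm38.p6) stood at 46.6 ± 10.7 CPM (SD, n = 6) in WT and 72.5 ± 7.94 CPM (SD, n = 6) in cKO, a log2 fold change of 0.67 (SE 0.119). The WT libraries ran from 35.9 to 58.6 CPM and the cKO libraries from 59.2 to 80.8 CPM, so all 6 cKO libraries lay above all 6 WT libraries. The log2 fold change was 0.56 in library set 1 and 0.75 in set 2. An exact permutation test of log2 CPM gave p = 0.00216 over 924 splits and p = 0.00286 over the 350 splits within library sets, both two-sided. Over all genes edgeR gave an adjusted p of 0.265, which ran from 0.0376 (without WT replicate 6) to 0.982 (without WT replicate 5) with 1 library left out and was 0.915 with embryo sex as a covariate, while DESeq2 gave 9.24e-04. Whole-gene counts do not isolate the deleted part of a conditional allele, so these levels check nothing about the knockout. The other m3C enzymes and the partner genes did not pass the threshold: log2 fold changes were -0.01 (SE 0.133) for Mettl2, -0.05 (SE 0.0586) for Mettl6, 0.12 (SE 0.249) for Dalrd3 and -0.02 (SE 0.0457) for Sars. In this list of 5 measured genes 1 passed when adjusted over the list alone (Mettl8, adjusted p = 0.000101, edgeR) and 0 over all genes. The list had a median of -0.01 (0.03 in set 1 and 0.0066 in set 2) but a mean of 0.14, and camera placed it upward without a call (adjusted p = 0.238).

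No gene passed the threshold over all 13105 genes in edgeR. At an unadjusted p under 0.05 there were 375 genes higher and 430 lower in cKO, 805 in all. Other splits of the 12 libraries into 6 and 6 gave 254 to 1696 genes at this level. The number alone is therefore no sign of a genotype effect. DESeq2 called 2 genes, Mettl8 and Dio2, and limma-voom called 1, growth hormone (Gh). Without a filter on low counts edgeR called 20 genes higher and 45 lower, among them the Y-linked Kdm5d, Eif2s3y, Uty and Ddx3y (higher) and Xist and Tsix (lower), which were named after their values were seen and of which the Y-linked genes were read mainly in 2 male cKO libraries. Dio2, a deiodinase that activates thyroid hormone (chromosome 12, 90724552 to 90739038), was chosen after its values were seen. It stood at 219 ± 25.7 CPM (SD, n = 6) in WT and 154 ± 33.1 CPM (SD, n = 6) in cKO, a log2 fold change of -0.53 (SE 0.112) with an adjusted p of 0.803 in edgeR and 0.0337 in DESeq2. Its log2 fold change was -0.43 in set 1 and -0.61 in set 2. Dio2, Mettl8 and Gh were also among the genes that edgeR called without the filter (adjusted p = 1.63e-13, 1.96e-12 and 1.75e-07).

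Gh, a pituitary hormone gene (chromosome 11, 106300261 to 106303703), was also chosen after its values were seen. The 6 cKO libraries had 27, 17, 22, 23, 31 and 39 Gh counts. Of the 6 WT libraries, 5 had 0, which allows up to 0.199 CPM, and WT replicate 3 had 22. Levels were 0.242 ± 0.592 CPM (SD, n = 6) in WT and 1.81 ± 0.438 CPM (SD, n = 6) in cKO. The edgeR adjusted p was 0.803, and 0.000391 without WT replicate 3, where Gh was called. In library set 2 alone, which lacks that library, edgeR called Gh and Zfp277 (adjusted p = 0.0122 for each). By edgeR's smallest p, also chosen after the values were seen, the zinc finger gene Zfp941 (log2 fold change 0.61), the kinesin Kif4 (0.23) and Ttll4 (0.39) were higher. Ifitm3 (-0.25), Yif1a (-0.23), the extracellular glycoprotein Reln (-1.19), Fam19a2 (-0.997), Abca9 (-1.28) and the lysophosphatidic acid receptor Lpar1 (-0.83) were lower. None of them passed over all genes (edgeR adjusted p = 0.803 for each).

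**Figure D3:**
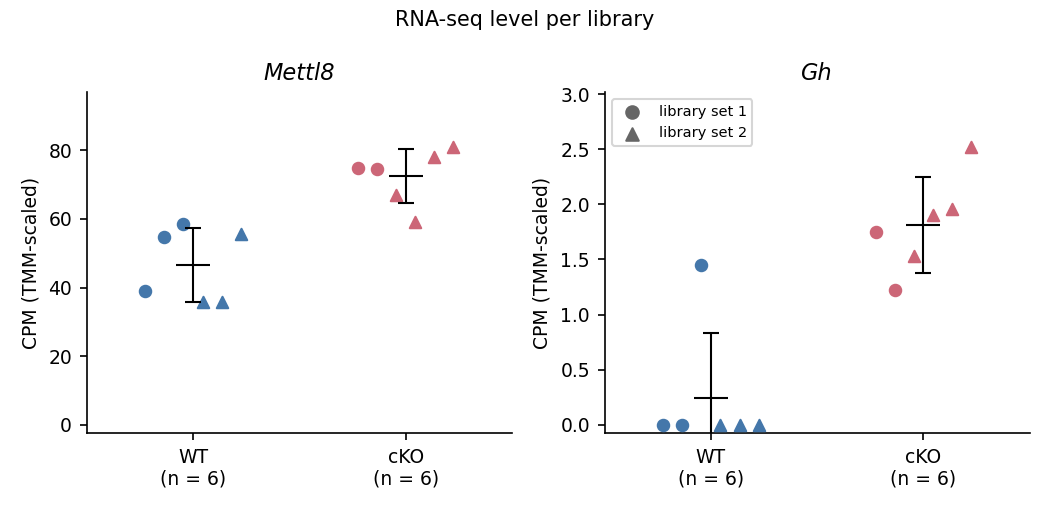
TMM-scaled CPM of Mettl8 and Gh in each RNA-seq library (circles, library set 1; triangles, library set 2), with the mean ± SD of 6 WT and 6 cKO libraries. Mettl8 runs from 35.9 to 58.6 CPM in WT and from 59.2 to 80.8 CPM in cKO, and Gh is above 0 in all 6 cKO libraries and in WT replicate 3.

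Of 23 gene lists tested by camera 7 passed at the preset correlation, 5 lower in cKO (respiratory chain, glycolysis and astrocytes) and 2 higher (cell cycle), and 0 passed with an estimated correlation (adjusted p = 0.522 to 0.608 for these 7). Among subunits of complexes II to V encoded in the nucleus 29 of 38 lay below 0 (median log2 fold change -0.09; -0.06 in set 1 and -0.10 in set 2), as for Sdha (-0.06, SE 0.0432), whereas Atp5a1 was at 0.03 (SE 0.0481). camera gave an adjusted p of 2.03e-08 and 0.522 with an estimated correlation, and all 6 cKO libraries scored below the WT mean of their set. Complex I followed, with 27 of 36 nuclear-encoded subunits below 0 (median -0.07; -0.08 in set 1 and -0.06 in set 2), including Ndufc2 (-0.07, SE 0.0471) and Ndufv2 (-0.08, SE 0.046). Its adjusted p was 9.37e-05, and 0.522 with an estimated correlation, with 4 of 6 cKO libraries below the WT mean. All 7 measured mRNAs encoded in mitochondrial DNA lay below 0 (median -0.08; 0.0013 in set 1 and -0.14 in set 2), among them mt-Cytb (-0.08, SE 0.0373) and mt-Co1 (-0.03, SE 0.0593). The adjusted p was 0.0151, and 0.522 with an estimated correlation, and 5 of 6 cKO libraries lay below. That call was lost without cKO replicate 3 (adjusted p = 0.248) or WT replicate 5 (0.164), and in set 1 alone its direction turned (0.67). The other 6 mitochondrial mRNAs were at most at 0.169 CPM and not tested, while mt-Cytb stood at 10050 CPM in WT. Whether reads of these 6 were lost in mapping or counting was not tested. The list result therefore covers the 7 measured mRNAs only.

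Glycolytic genes lay below 0 in 16 of 19 cases (median -0.11; -0.10 in set 1 and -0.12 in set 2), with Ldha, a lactate dehydrogenase subunit, at -0.11 (SE 0.0658) and Aldoa at 0.0029 (SE 0.0784). The adjusted p was 3.47e-04, and 0.522 with an estimated correlation, with 4 of 6 cKO libraries below the WT mean. It rose to 0.948 without the library set term and to 0.0766 with embryo sex as a covariate. All 13 astrocyte markers, each of which these NPC cultures expressed, lay below 0 (median -0.10; -0.0083 in set 1 and -0.21 in set 2), among them Sparcl1 (-0.03, SE 0.0905) and Gja1 (-0.15, SE 0.141). The adjusted p was 0.00248, and 0.59 with an estimated correlation, with 4 of 6 cKO libraries below. The call was lost without cKO replicate 4 (0.193) or WT replicate 5 (0.0511) and with embryo sex as a covariate (0.0536).

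All 20 mitotic genes of the G2/M list lay above 0 (median 0.10; 0.035 in set 1 and 0.16 in set 2), and all 6 cKO libraries scored above the WT mean of their set. Top2a, the mitotic DNA topoisomerase, was at 0.12 (SE 0.0424) and the proliferation marker Mki67 at 0.18 (SE 0.0544), 582 ± 22.6 CPM (SD, n = 6) in WT and 666 ± 61.2 CPM (SD, n = 6) in cKO. The mitotic kinase Plk1, chosen after its values were seen, was at 0.45 (SE 0.138). camera gave an adjusted p of 5.55e-09, and 0.522 with an estimated correlation, and in set 1 alone the adjusted p was 0.168. Of the 20 genes, 2 passed when adjusted over the list alone (Mki67 and Plk1, edgeR adjusted p = 0.043 for each) and 0 over all genes. In the G1/S list 17 of 20 genes lay above 0 (median 0.06; -0.04 in set 1 and 0.16 in set 2), including the ribonucleotide reductase subunits Rrm1 (0.07, SE 0.0488) and Rrm2 (0.04, SE 0.0493). The adjusted p was 0.00287, and 0.608 with an estimated correlation, and only 3 of 6 cKO libraries lay above the WT mean. The G1/S call was lost without cKO replicate 4 (0.247) or WT replicate 5 (0.0797), and in set 1 alone its direction turned (0.331). Scores are means of log2 CPM over a list's genes, centred within each library set, so they do not rank libraries across sets. Within set 2 cKO replicate 4 scored highest on G2/M (0.172) and G1/S (0.294) and lowest on the astrocyte (-0.661) and oligodendrocyte (-0.878) lists. In the same set WT replicate 5 scored lowest on G1/S (-0.156) and highest on the astrocyte (0.402) and oligodendrocyte (0.611) lists. The smallest adjusted p of fry was 0.315. In the 6 called lists other than G2/M, 0 genes passed adjusted over the list alone and 0 over all genes. Embryo sex differed between genotypes: 2 of the 6 cKO libraries (replicates 1 and 5) had no Xist read and 10548 and 10363 Y-linked counts, while no WT library lacked Xist.

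**Figure D4:**
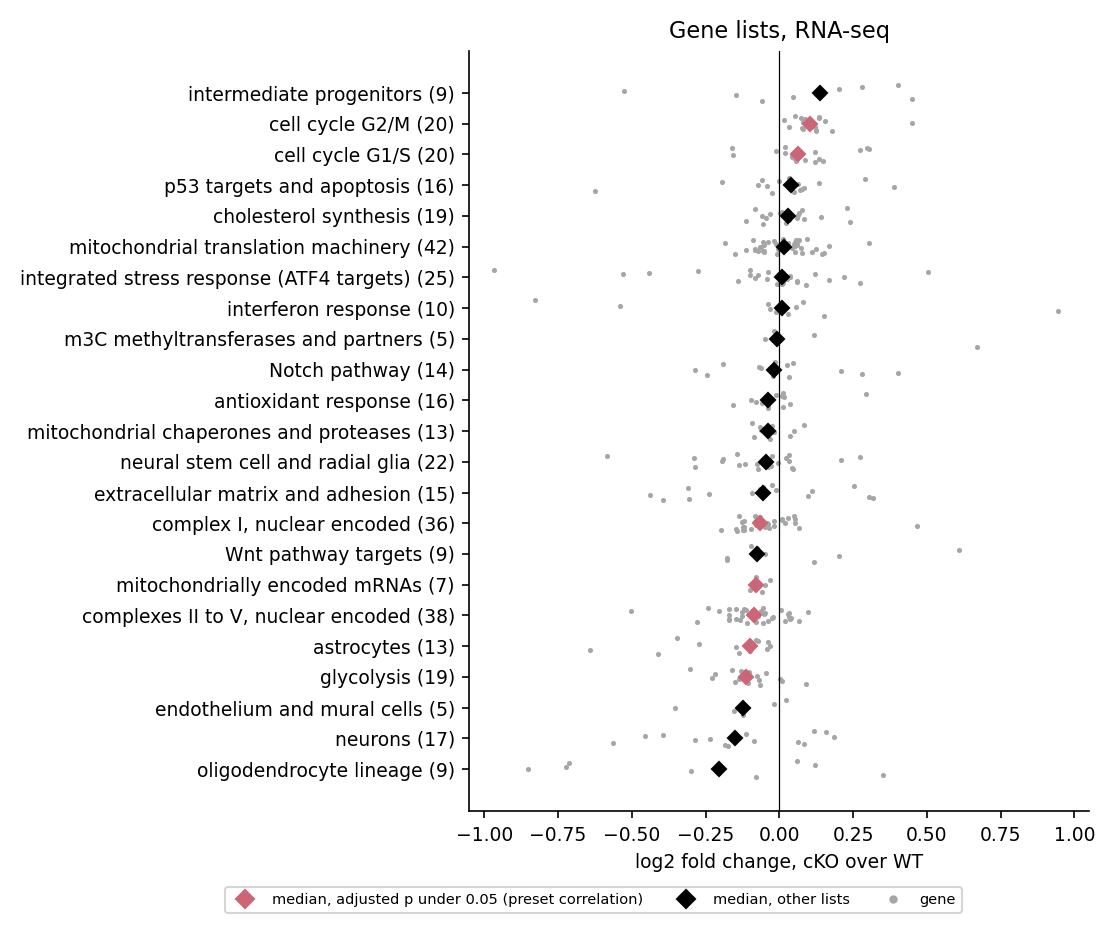
Log2 fold change (cKO over WT) of each measured gene (grey points) in the 23 tested lists, with the number of measured genes in parentheses. Diamonds mark the median of each list, red for the 7 lists with an adjusted p under 0.05 at the preset correlation, from -0.11 for glycolysis to 0.10 for G2/M.

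Markers of the stem cell state and its progeny did not pass the threshold as groups. Of 22 neural stem cell and radial glia genes 15 lay below 0 (median -0.04; 0.02 in set 1 and -0.08 in set 2; camera adjusted p = 0.21, and 0.0433 without cKO replicate 1), with Fabp7 at -0.14 (SE 0.0665) and the glutamate transporter Slc1a3 at -0.12 (SE 0.0831). Of 9 intermediate progenitor genes 6 lay above 0 (median 0.14; 0.10 in set 1 and 0.16 in set 2; adjusted p = 0.21), with Elavl4 at 0.14 and Btg2 at -0.06. Neuronal genes lay below 0 in 12 of 17 cases (median -0.15; 0.02 in set 1 and -0.23 in set 2; adjusted p = 0.0848), with Mapt, the tau gene, at -0.16 and Gap43 at 0.19. The neuronal list was called lower in set 2 alone (0.00654), with embryo sex as a covariate (0.0356) and without WT replicate 1 (0.0413), WT replicate 5 (0.0419), cKO replicate 1 (0.0385) or cKO replicate 4 (0.0324). These calls used camera's preset correlation, and with all libraries and an estimated correlation the neuronal list had an adjusted p of 0.522. Of 9 oligodendrocyte lineage genes 6 lay below 0 (median -0.20; 0.06 in set 1 and -0.29 in set 2; adjusted p = 0.381, and 0.044 without WT replicate 4), among them Pdgfra (-0.08, SE 0.126). Endothelial and mural markers included Acta2 (-0.02) and Tagln (0.02), with 4 of 5 below 0 (median -0.12; 0.25 in set 1 and -0.30 in set 2; adjusted p = 0.613). In each of these lists 0 genes passed adjusted over the list alone and 0 over all genes (edgeR). Some lists were too little expressed to test, with 4 measured genes each in the ventral and interneuron lineage (highest Olig1, 130 CPM) and in meningeal fibroblasts (highest Pdgfra, 239 CPM), 3 in ependyma (highest Dynlrb2, 2.49 CPM) and 1 in microglia (P2ry12, 4.33 CPM). The X inactivation list (2 genes, Xist and Tsix) and the Y-linked list served only as a check of sex.

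Stress and signalling groups also stayed on the other side of the threshold. ATF4 targets of the integrated stress response split, 13 above and 12 below 0 (median 0.0086; 0.02 in set 1 and -0.02 in set 2; mean -0.05, camera downward, adjusted p = 0.779), with Psat1 at 0.06 and Asns at 0.01. The mitochondrial translation machinery had 23 of 42 genes above 0 (median 0.01; -0.03 in set 1 and 0.05 in set 2; adjusted p = 0.779), with the leucyl-tRNA synthetase Lars2 at -0.18 (SE 0.0662). Lars2 stood at 7179 CPM in WT, against 194 CPM for Rars2, the next highest of this list. Whether all reads counted for Lars2 came from its mRNA was not tested. Mitochondrial chaperones and proteases had 10 of 13 below 0 (median -0.04; adjusted p = 0.487), with Hspd1 at -0.03. Antioxidant genes had 10 of 16 below 0 (median -0.04; -0.07 in set 1 and 0.0011 in set 2; adjusted p = 0.613). Cholesterol synthesis genes had 13 of 19 above 0 (median 0.03; -0.0026 in set 1 and 0.04 in set 2; adjusted p = 0.546, and 0.0279 without the library set term), with Hmgcs1 at -0.06. p53 targets had 10 of 16 above 0 (median 0.04; 0.02 in set 1 and 0.04 in set 2; adjusted p = 0.21), with Eda2r at 0.14. Adjusted over the list alone, 1 antioxidant gene (Gsr, 0.29, edgeR adjusted p = 0.0496) and 1 p53 target (Pmaip1, 0.39, adjusted p = 0.0301) passed, both chosen after their values were seen, with 0 in either list over all genes. Notch genes had 8 of 14 below 0 (median -0.02; 0.0099 in set 1 and 0.02 in set 2; mean 0.0053, camera upward, adjusted p = 0.917), with Rbpj at 0.05 and Notch1 at 0.03. Wnt targets had 6 of 9 below 0 (median -0.08; -0.15 in set 1 and 0.03 in set 2; mean 0.03, camera downward, adjusted p = 0.681), with Tcf7l2 at -0.10. Interferon genes split 5 to 5 (median 0.0080; 0.20 in set 1 and -0.26 in set 2; mean -0.02, camera downward, adjusted p = 0.779), with Ddx58 at -0.04. Extracellular matrix genes had 10 of 15 below 0 (median -0.06; -0.05 in set 1 and -0.02 in set 2; adjusted p = 0.633), with Itgb1 at -0.01. In the lists of this paragraph other than antioxidant genes and p53 targets, 0 genes passed adjusted over the list alone and 0 over all genes.

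The effect of genotype was also compared between the library sets. edgeR called 0 genes for the interaction of genotype and set. Of 13105 genes, 464 had an unadjusted p under 0.05, where chance alone would give a share of about 0.05. The smallest p belonged to Zfp277, chosen after its values were seen, whose log2 fold change was -0.08 in set 1 and 0.97 in set 2. The difference was 1.06 (SE 0.195), with an adjusted p of 0.474 in edgeR and 0.00973 in DESeq2, where it was the 1 gene called among 540 at an unadjusted p under 0.05. Without cKO replicate 3 edgeR called Wdfy1 (adjusted p = 0.00185), also chosen after its values were seen.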

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

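The tests of correlated genes, of RNA mixed in from a male cKO library, of a wrong label, of more mt-tRNA-Ser(UCN) molecules, of lists matched to complex I and of sites of similar cleavage were chosen only after the result was seen. Of 198 groups of values from the libraries of 1 genotype, 7 had 1 library far from the others, and chance sets about 1 in 20 groups apart. These were Gh in WT replicate 3 (1.45 CPM among WT libraries otherwise at 0), and in cKO replicate 3 the scores of the mitochondrially encoded mRNAs (-0.215) and of Wnt targets (0.236). In HAC-seq they were cleavage at mt-Tt in WT replicate 1 (93.7%), at mt-Ts1 in WT replicate 4 (1.25%) and at the Rbl1 site in WT replicate 3 (98.7%), and the coverage of tRX-Lys-NNN-22-1 in WT replicate 1 (100 reads). Signals outside the comparisons were Y-linked counts of 10548 in cKO replicate 1, 10363 in cKO replicate 5 and 97 in WT replicate 3, against at most 4 in the other libraries. Another was the coverage at mt-tRNA-Ser(UCN) position 32, 5.78 times higher in cKO.

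Gh was read in all 6 cKO libraries and, of the WT libraries, in replicate 3 alone, at 79.0% of the cKO level (48.2% to 124%). RNA of a male cKO library mixed into WT replicate 3 was argued against, since its Y-linked reads reached only 0.952% of the male cKO level (0.772% to 1.16%). A wrong label or RNA of a female cKO library cannot be told apart from a true WT library: Mettl8 in WT replicate 3 differed by -0.681 CPM from the lowest cKO library, less than the SD of 10.1 CPM of the other WT libraries. A candidate explanation, as a hypothesis, is a transgene with growth hormone sequence, such as a Cre construct, in the cKO embryos and in the embryo of WT replicate 3. It was not tested, since the labels name no Cre line and gene counts do not separate transgene from endogenous Gh reads.

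The lists of complex I, complexes II to V, G1/S and G2/M passed the threshold at the preset correlation. With embryo sex as a covariate 4 of the 4 lists still passed at the preset correlation. Lists called at this correlation did not pass with an estimated one, and the 2 male libraries were cKO. The covariate therefore does not decide whether sex was part of the cause. For the 2 respiratory chain lists, lower levels of abundant mRNAs in general were argued against. Of 10000 lists matched on mean expression 0 had a median as low as the -0.09 of complexes II to V, and 0 of 10000 one as low as the -0.07 of complex I. The lists were matched on mean expression only, so this says nothing about genes that vary together. Genes that vary together between cultures remain open and may account for the shift: 0 of the 4 lists passed with the correlation estimated from the libraries, and 25 of the other splits of the libraries called at least 7 lists, the number that the real split called. A biological effect of genotype also stays open and is not separated from this.

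Coverage at mt-tRNA-Ser(UCN) position 32 was higher in cKO while its cleaved reads were absent there. Library depth was argued against, since scaled coverage at sites of 16 other mt-tRNAs had a 95th percentile of 1.23 (cKO over WT), although these leave out mt-tRNA-Thr, where it was 14.7 and 16.5 times higher at positions 15305 and 15312. The listing of sites by reads in WT libraries only was argued against for the missing cleaved reads, since 1 of 19086 other sites with WT cleavage of at least 1% and at least 1000 cKO reads, and 1 of the 13825 of them cleaved at 0.5 to 2 times the level of this site, had no cKO read start, and that 1 is the copy in Myo3a. More mt-tRNA-Ser(UCN) molecules in cKO cannot be told apart from loss of cleaved fragments in WT, since the table lists 0 sites 3 prime of position 32 in this gene. As a hypothesis, cleaved fragments of this tRNA may have been lost before counting, in which case the WT ratio of 2.55% would be too low.

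Other splits of the libraries were scored in the same way. For HAC-seq sites 1 of 35 splits, the real one, called 1 site and the highest of the others called 0. A share of 1 in 35 (0.0286) is the smallest that this design allows. Every other split puts WT and cKO libraries on the same side, so mt-tRNA-Thr could hardly be called in it. The comparison shows that the call goes with the genotype labels and does not exclude chance. For RNA-seq genes the real split called 0, a number that all 100 of 100 splits reached, so the comparison decides nothing, and the highest of the others called 24. For gene lists 26 of 100 splits called at least the real number of 7, with 10 as the highest of the others, so chance cannot be excluded.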

How the results depend on the processing

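Sex as a covariate, leaving out the 2 male libraries, counts divided by 2, limma-voom, 1 site per distinct set of counts, a mean ratio of at least 0.01 and nucleotide 32 only were chosen after seeing the data. Mettl8 kept its direction under all 25 alternatives (log2 fold change 0.56 to 0.78) and cytosolic tRNA cleavage stayed on the same side of its threshold under all 12 (from 0.0768 points for the median over sites to 3.04 for nucleotide 32 only). Of 1621 values of named genes 1610 stayed on the same side of the threshold, some with another sign, and 11 passed it newly. All 91 values of the named sites other than position 32 of mt-tRNA-Thr and mt-tRNA-Ser(UCN) stayed on their side, and of 460 list values 424 did, 12 were gained, 22 were lost in the same direction and 2 were lost with the direction reversed.

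Against 0 genes called by edgeR, DESeq2 called 1 higher and 1 lower, limma-voom 1 higher, no filter on low counts 20 higher and 45 lower, and library set 2 alone 2 higher, and leaving out 1 library gave 0 to 1 higher and 0 lower. Other settings gave 0. The cause was not tested, except that WT replicate 3 is the 1 WT library with Gh reads and that the genes called without a filter included 4 Y-linked genes, Xist and Tsix. For the interaction DESeq2 called 1 gene higher in set 2, and leaving out 1 library gave 0 to 1. Against 2 lists higher and 5 lower, the estimated correlation gave 0 and 0 and library set 1 alone, with 5 libraries, 0 and 2. Leaving out 1 library gave 1 to 2 higher and 4 to 7 lower. In set 1 alone the mitochondrially encoded mRNAs (adjusted p = 0.67) and the G1/S list (0.331) reversed. The cause was not tested.

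Among HAC-seq sites 1 was lower and 0 higher. A mean ratio of at least 0.01 gave 4 lower, which adds mt-Ts1 (adjusted p = 8.67e-04) and its Myo3a copy, admitted by it, and a CT010467.1 site (0.0311) that was tested before, and leaving out 1 library gave 1 to 13 lower and 0 to 17 higher, the highest without cKO replicate 2. The cause was not tested. The difference at mt-tRNA-Thr was -92.6 to -92.1 points with 1 library left out and -92.2 with a replicate block. At mt-tRNA-Ser(UCN) it was -2.99 to -2.36 and -2.99. Exact one-sided p-values of 0.05 to 0.0667 and of 0.125 in these are the smallest that so few libraries allow.

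The labels do not tie a replicate number to a shared animal, litter or day, and not every same-numbered correlation was over 0.1, so the numbers were not taken as pairs. Correlations of same-numbered libraries were 0.514, 0.621, -0.359, 0.437, 0.383 and 0.373 in RNA-seq, where number 3 joins libraries of different sets and 2 of 6 correlated best with their own number, and -0.00794, -0.0177 and 0.0355 in HAC-seq, where 1 of 3 did. With the number as a block in place of the library set 0 genes were called, glycolysis was lost (0.714) and cholesterol synthesis (0.00269) and the oligodendrocyte lineage (0.00594) were gained. Leaving out the set term alone also lost glycolysis (0.948) and gained cholesterol synthesis (0.0279). In HAC-seq the block, with WT replicate 4 left out, called the same site.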

Other observations

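Coverage along mt-tRNA-Thr differed between genotypes at the listed sites upstream of position 32. Reads cleaved at position 32 start downstream of these sites and do not cover them. The difference is therefore another view of the cleavage at position 32 and not a separate result. At positions 15305 and 15312 of chromosome MT, 5 prime of the site, scaled coverage was 118 ± 32 and 141 ± 37.7 (SD, n = 4) in WT and 1740 ± 174 and 2330 ± 348 (SD, n = 3) in cKO, 14.7 and 16.5 times higher (exact permutation p = 0.0286 for each, two-sided). At position 32 itself it was 0.865 times the WT level (exact permutation p = 0.686, two-sided). Over 69 sites in 16 other mt-tRNAs the ratio had a median of 0.992 and ran from 0.63 to 1.25, with the highest value in mt-Tm. At 81 sites in the mitochondrial ribosomal RNAs mean cleavage was 7.67% in cKO replicate 3 and 13.4% to 16.1% in the other 6 HAC-seq libraries.

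The library sets lay apart in a glial and a cell cycle gene, in both genotypes. Gja1, the main gap junction gene of astrocytes, was at 719 to 1185 CPM in the 5 libraries of set 1 and at 147 to 291 CPM in the 7 of set 2. The cyclin gene Ccnd1 was at 93.2 to 143 CPM in set 1 and at 247 to 291 CPM in set 2. Within set 2 cKO replicate 4 had the lowest scores of the astrocyte (-0.661) and oligodendrocyte (-0.878) lists, and WT replicate 5 the highest (0.402 and 0.611). No test was made of these values.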
